A study of Mus musculus with 40 samples.

How the data were processed

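Lung RNA from 40 female C57BL/6 mice was compared on 2-colour Agilent mouse arrays. Per the labels, the mice had received a single intratracheal instillation of vehicle (0 µg) or of 54, 162 or 486 µg of titanium dioxide nanoparticles, and lungs were taken on day 1 or day 28. Each of the 8 groups held 5 arrays. Lung RNA was in the Cy5 channel and a universal mouse reference RNA in the Cy3 channel of every array, so each value is the log2 ratio of lung over reference and a difference between groups cancels the reference. Other doses and times of the wider study were not analysed here. The arrays lay on 10 slides of 4 arrays, each slide with 1 array per dose of a single day, and were scanned on 3 days that held 16, 16 and 8 arrays and all 8 groups each. Replicate numbers name the arrays of a group only, and within a day each number falls on 1 slide.

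Per the file headers, the deposited scanner files were written by Agilent Feature Extraction 11.0.1.1, and they hold median signals and processed signals in intensity units. The deposited scanner files also hold a ratio column on the log10 scale. The deposited series value table is on the log2 scale. The labels at hand do not state how that table was scaled and centred. Its array medians lay between -0.0449 and -0.0267, and its correlation with loess-normalised ratios made here without background subtraction was 0.993 to 0.997 across probes of an array.

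The median signal of each channel was corrected for its median local background with the normexp method (offset 50), and ratios were loess-normalised within arrays in limma 3.58.1 (R 4.3.3 with data.table, version 1.17.8). Mean signals had been planned, but the files hold medians, which were used instead. Spots marked by the scanner software as non-uniform or population outliers were set to missing, and replicate spots were averaged. Of 45018 spots, 43379 were not controls and stood for 41174 probes, of which 245 were spotted 10 times. Probe accessions were matched to RefSeq mouse gene names, which gave a symbol to 27479 probes and left 13695 with an accession alone. A probe was kept when its Cy5 signal was well above background on at least 4 of the 5 arrays of at least 1 group, which kept 26567. The brightest probe stood for each gene, so 20031 items were tested, 14464 with a symbol and 5567 with only an accession. A gene with several kept probes (5118 items) can differ between them, and values of other probes are given where they part.

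The 8 group means were fitted with limma and empirical Bayes moderation (median total degrees of freedom 35.5), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each dose against 0 µg on each day, each dose against the next lower dose, the difference of each dose's response between day 28 and day 1, and day 28 against day 1 in the 0 µg mice. That last comparison lies between slides, so slide entered as a random block (correlation 0.234). Values after ± are limma standard errors beside log2 differences and standard deviations beside group means. Adjusted p-values without another test named come from limma. They measure the spread between samples of different mice, and with 5 arrays per group this number limits the precision.

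Gene lists for 40 pathways and cell types were fixed before the data were examined. They hold 702 genes, of which 610 were measured. 20 genes stand in more than 1 list. A list was tested against all other genes with camera at a preset inter-gene correlation of 0.01 over 19913 genes without missing values, with adjustment over the 40 lists, and again with a correlation estimated from the arrays. The fry test asked in addition whether a list's genes moved one way on balance. Counts adjusted over a list alone use only the p-values of its members.

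Genes were named by a rule that was also fixed before the data were examined. For each dose against 0 µg, it took the 10 highest and 6 lowest called genes with a symbol whose 5 treated arrays lay on the same side of the control mean. From each list called by camera or with at least 2 called members it took up to 4 members with the largest change. It also took 20 preset genes at 486 µg (Mmp12 did not pass the filter), and the 5 highest and 5 lowest called genes of the other comparisons. Some were left out for length. Items with only an accession are named where a count is small, after their values were seen.

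The alternatives were no background subtraction, the deposited ratio column, loess with quantile scaling of the intensities, median centring, the Cy5 channel alone, the deposited value table, other filters on dim probes, the mean of a gene's probes, slide or scan day as a block, a fit of only the groups compared, a minimum of 1.5-fold, and each array left out in turn. After the data had been examined, fits with liver genes or clock genes as a covariate and without arrays that held liver transcripts were added. The groups compared were also split at random 100 times, without regard to slide. After the data had been examined, the 16 splits that swap the compared arrays only within slides were added, with slide as a block. The code was tested on simulated data with 200 changed genes among 20031. For the 486 µg comparison on day 1, the share recovered was 55.2% at a log2 change of 0.5, 92.5% at 1 and 100% at 2, and 11 of 176 calls were false. Figures were drawn with matplotlib 3.10.9.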

Results

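Messenger RNA of mouse lung was measured after a single instillation into the trachea of titanium dioxide nanoparticles of 20 nm, a mixture of rutile and anatase. Female C57BL/6 mice received 0, 54, 162 or 486 µg, and lungs were examined after 1 or 28 days, with 5 arrays in each of the 8 groups and RNA from random sections of each lung. The median lung-channel signal of an array lay between 109 and 144.5 intensity units over a median background of 69 to 83, and 57.2% to 68.5% of probes were well above background. No lung-channel spot was saturated. Correlations between arrays, across genes, ranged from 0.830 to 0.980. The comparisons ask which transcripts change with dose shortly after exposure, which differences are present after 28 days, and whether the response differs between the days.

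At 54 µg on day 1, some transcripts of acute phase proteins and chemokines were higher than in vehicle controls, 4 of 18 and 2 of 17 in the preset lists of acute phase genes and CC chemokines. Saa3, a serum amyloid A protein made in inflamed lung, was higher by 4.19 ± 0.74 on the log2 scale (n = 5 per group, adjusted p = 0.0053), with 4 of the 5 treated arrays above the control mean and replicate 1 at -3.2. Saa1, another serum amyloid A, was higher by 2.58 ± 0.35 (adjusted p = 0.00029) on all 5 slides. Timp1, an inhibitor of matrix metalloproteinases, was higher by 2.62 ± 0.44 (adjusted p = 0.0053), with 4 of the 5 treated arrays above the control mean and replicate 1 at -3.15. Ccl17, a chemokine that attracts T cells, rose by 1.44 ± 0.25 and Ch25h, which makes 25-hydroxycholesterol, by 1.39 ± 0.25, each with an adjusted p of 0.0053 and on all 5 slides. Lcn2, an iron-siderophore-binding protein of neutrophils and epithelium, was higher by 2.13 ± 0.46 (adjusted p = 0.034) on 4 of 5 slides, a call that ended in 9 of 10 fits with 1 array left out. Among the genes lower at this dose were Neat1, a long noncoding RNA of nuclear paraspeckles (-0.54 ± 0.10, adjusted p = 0.013), and Rbm5, a splicing factor (-0.31 ± 0.06, adjusted p = 0.0075). Eif4b, a translation initiation factor, was lower by one probe (-0.38 ± 0.07, adjusted p = 0.0053), while its other probes gave -0.06 and 0.08. All 3 were lower on all 5 slides, and the calls of Neat1 and Rbm5 ended without 0 µg replicate 2, that of Neat1 also without 54 µg replicate 3.

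In all, 34 genes were called at 54 µg on day 1, 29 higher and 5 lower, and 16 of them changed at least 1.5-fold. Of 17 CC chemokines, 2 rose in the test over all genes and 11 passed when adjusted over the list alone. As a group they shifted upward on all 5 slides, with a median of 0.64 (camera adjusted p = 1.15e-11), and this was the one list of 13 called by camera that held its call with an estimated correlation (adjusted p = 0.0351). Of 18 acute phase genes, 4 rose and 7 passed when adjusted over the list alone (median 0.38, camera adjusted p = 1.75e-08; adjusted p = 0.112 with an estimated correlation). Neutrophil markers had no called gene among 19, 4 when adjusted over the list alone, and a median of 0.37 (camera adjusted p = 2.65e-05; adjusted p = 0.164 with an estimated correlation). Xenobiotic metabolism genes shifted downward, with none of 19 called, 2 when adjusted over the list alone and a median of -0.26 (camera adjusted p = 8.28e-05; adjusted p = 0.164 with an estimated correlation). With slide as a block 163 genes were called, 115 higher and 48 lower. Leaving out 1 array gave 53, 10, 20 and 20 genes without 0 µg replicates 1, 2, 4 and 5, and 81, 10, 13 and 76 without 54 µg replicates 1, 3, 4 and 5. Camera called 8 lists without 0 µg replicate 1 and 7 without 54 µg replicate 5.

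At 162 µg on day 1 some acute phase and chemokine transcripts were higher again and genes of cholesterol synthesis rose as a group. Saa3 was 32.8-fold above vehicle (5.03 ± 0.74 on the log2 scale, n = 5, adjusted p = 0.00015) and Timp1 11-fold (3.46 ± 0.44, adjusted p = 9.7e-06). The monocyte-attracting chemokines Ccl2 and Ccl7 rose by 2.00 ± 0.33 (adjusted p = 0.00055) and 1.88 ± 0.33 (adjusted p = 0.0011). The neutrophil-attracting chemokine Cxcl1 rose by 1.54 ± 0.30 (adjusted p = 0.0039) and Il33, a cytokine released by damaged epithelium, by 1.13 ± 0.20 (adjusted p = 0.0013). Sc5d and Fdps, both enzymes of the sterol pathway, rose by 0.40 ± 0.09 (adjusted p = 0.01) and 0.59 ± 0.13 (adjusted p = 0.012). Aldh1a1, a retinaldehyde dehydrogenase, fell by 0.74 on the log2 scale (SE 0.17, adjusted p = 0.017). Each of these 9 genes went the same way on all 5 slides. The Aldh1a1 call ended without 0 µg replicate 2 or 162 µg replicate 2, and the Fdps call without 162 µg replicate 5.

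There were 210 called genes at 162 µg, 166 higher and 44 lower, of which 62 changed at least 1.5-fold. Of 21 cholesterol synthesis genes 5 rose, 13 when adjusted over the list alone (median 0.39, camera adjusted p = 2.7e-15). Of 18 acute phase genes 5 rose, 10 when adjusted over the list alone (median 0.69, camera adjusted p = 5.82e-16). Of 17 CC chemokines 5 rose, 7 when adjusted over the list alone (median 0.44, camera adjusted p = 5.41e-09). Matrix proteases and inhibitors shifted upward with 2 of 20 called, 6 when adjusted over the list alone (median 0.24, camera adjusted p = 1.45e-05), as did metal and iron handling genes with 2 of 16 called, 3 when adjusted over the list alone (median 0.27, camera adjusted p = 1.9e-05), and inflammatory cytokines with 1 of 12 called, also 1 when adjusted over the list alone (median 0.21, camera adjusted p = 7.66e-05). Thymocyte genes shifted downward on all 5 slides with none of 4 called, 2 when adjusted over the list alone (median -0.43, camera adjusted p = 0.00836). These 7 lists, of 14 called by camera, held with an estimated correlation (adjusted p from 0.000387 for cholesterol synthesis to 0.0423 for thymocyte genes). Among those that did not hold were cell cycle genes, 1 of 31 called and 3 when adjusted over the list alone (median 0.25, camera adjusted p = 2.81e-06; adjusted p = 0.512 with an estimated correlation). With slide as a block 492 genes were called, and the count was 94, 139 and 135 without 0 µg replicates 2, 3 and 5 and 118 and 113 without 162 µg replicates 2 and 5. Without background subtraction 228 genes were higher and 104 lower, by the Cy5 channel alone 200 and 95, and with median centring 11 and 0.

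At 486 µg on day 1 the response was broadest, with acute phase, metal handling, matrix protease and cholesterol synthesis lists higher. Some lymphocyte genes were lower, but their lists lost the camera call with an estimated correlation. Saa3 was 68.3-fold above vehicle (6.09 ± 0.74, adjusted p = 5.5e-07), with a mean log2 ratio of 3.41 ± 0.49 against -2.68 ± 0.79 in controls (SD, n = 5 each). Timp1 was 21.5-fold higher (4.42 ± 0.44, adjusted p = 1.2e-08) and Saa1 12.3-fold (3.62 ± 0.35, adjusted p = 9.1e-09). Mt2, a metallothionein that binds zinc and other metals, was 11-fold higher (3.46 ± 0.36, adjusted p = 3.4e-08), and Lcn2 8.72-fold (3.13 ± 0.46, adjusted p = 1.1e-05). Sprr1a, a precursor of the cornified envelope of squamous epithelium, was 9.18-fold higher (3.20 ± 0.31, adjusted p = 7.3e-09), and Pbp2 10.6-fold (3.41 ± 0.24, adjusted p = 6.4e-12). Among lower genes were Ms4a1, which encodes the B cell surface protein CD20 (-1.25 ± 0.24, adjusted p = 0.00034), and Abcg1, a sterol exporter (-1.06 ± 0.18, adjusted p = 7.7e-05). All 9 went the same way on all 5 slides, as did the other called genes named for this dose unless a smaller number is given.

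**Figure D1:**
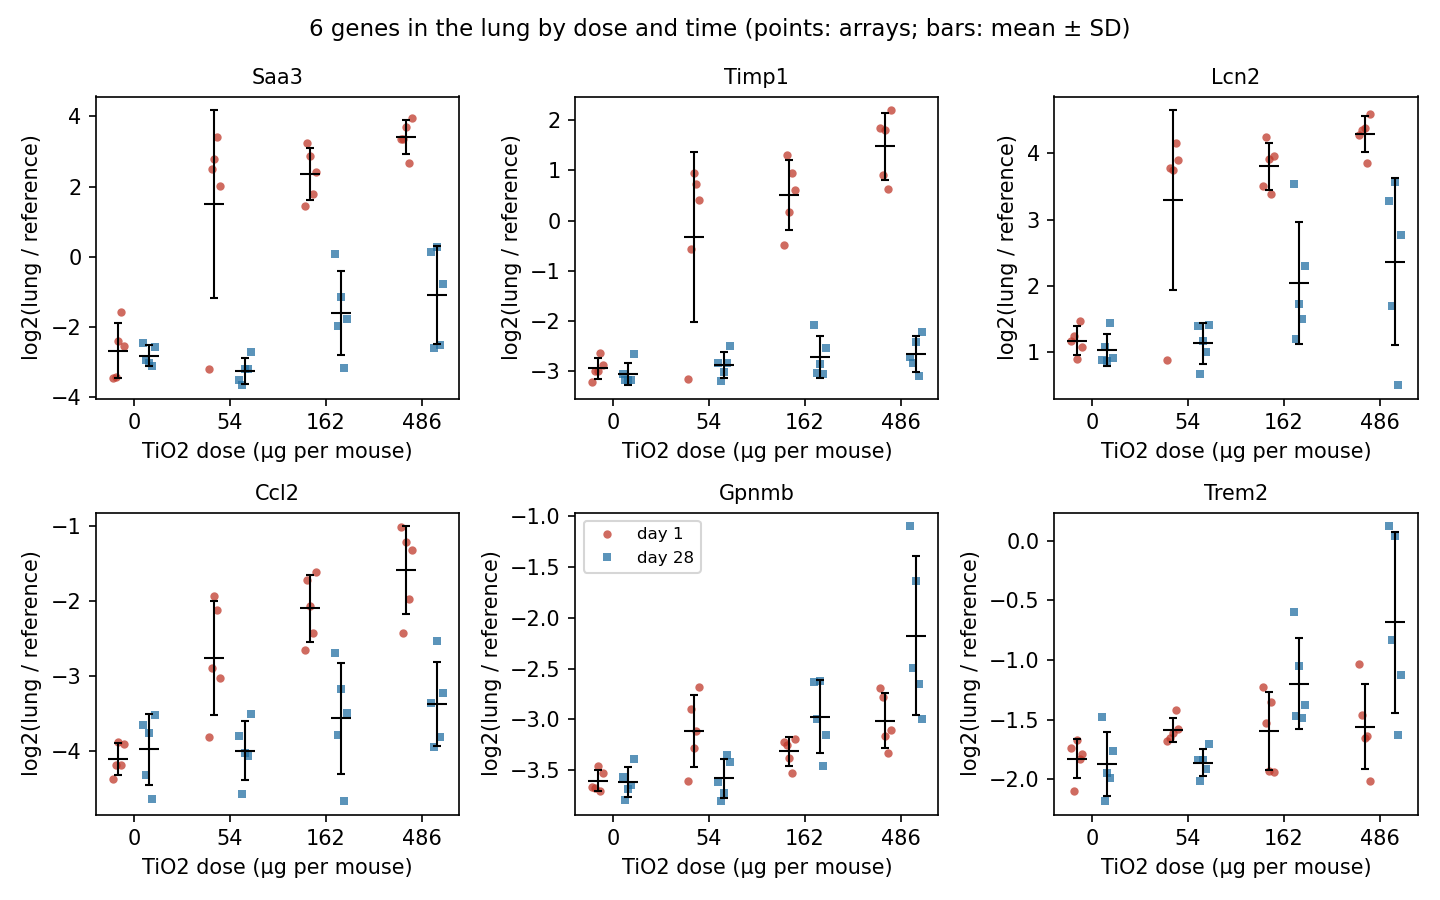
Log2 ratio of lung over reference RNA (y axes) of Saa3, Timp1, Lcn2, Ccl2, Gpnmb and Trem2 against dose in µg per mouse (x axes, evenly spaced, not to scale), where each point is an array (circles day 1, squares day 28) and bars are the mean and standard deviation of the 5 arrays of a group. On day 1 Saa3 rose from a mean of -2.68 at 0 µg to 3.41 at 486 µg, and on day 28 Gpnmb lay at -3.62 at 0 µg and -2.18 at 486 µg.

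Of 18 acute phase genes at 486 µg on day 1, 12 rose and none fell, 14 passing when adjusted over the list alone, with a median of 1.20 (camera adjusted p = 1.02e-13). Of 21 cholesterol synthesis genes 14 rose and none fell, 17 when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.02e-13). They included Hsd17b7 (1.11 ± 0.20, adjusted p = 2e-04), the synthase Lss (0.86 ± 0.13, adjusted p = 2.7e-05) and squalene epoxidase Sqle (0.85 ± 0.14, adjusted p = 4.1e-05). Fdft1, squalene synthase, rose by one probe (0.86 ± 0.13, adjusted p = 2.9e-05), while another gave 0.03. Matrix proteases and inhibitors had 11 of 20 higher and 1 lower, 14 when adjusted over the list alone (median 0.53, camera adjusted p = 1.29e-06). A member was Mmp3, stromelysin 1 (1.52 ± 0.23, adjusted p = 2.1e-05). Of 16 metal and iron handling genes 7 rose and none fell, 8 when adjusted over the list alone (median 0.57, camera adjusted p = 1.49e-06), with the metallothionein Mt1 up by 1.46 ± 0.20 (adjusted p = 2.8e-06). These 4 lists were higher on all 5 slides and were the ones of 19 called by camera that held with an estimated correlation (adjusted p = 0.011, 0.000771, 0.00263 and 0.011).

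Of 19 neutrophil markers 8 rose and 11 passed when adjusted over the list alone (median 0.54, camera adjusted p = 3.17e-05; adjusted p = 0.235 with an estimated correlation). Il1r2, the decoy receptor of interleukin 1, rose by 1.85 ± 0.28 (adjusted p = 2.2e-05), and Retnlg, a resistin-like protein of neutrophils, by 1.35 ± 0.32 (adjusted p = 0.0037). Of 17 CC chemokines 5 rose and 1 fell, 9 when adjusted over the list alone (median 0.57, camera adjusted p = 0.00221; adjusted p = 0.347 with an estimated correlation), with Ccl2 5.7-fold higher (2.51 ± 0.33, adjusted p = 2.1e-06). Of 32 collagens and structural matrix genes 7 rose and 1 fell, 13 when adjusted over the list alone (median 0.24, camera adjusted p = 0.00244; adjusted p = 0.431 with an estimated correlation). Tnc, tenascin C of injured matrix, was 3.47-fold higher (1.80 ± 0.24, adjusted p = 3.4e-06) and Col4a1, a basement membrane collagen, rose by 1.08 ± 0.21 (adjusted p = 0.00064). Of 11 glucocorticoid-responsive genes 5 rose, 6 when adjusted over the list alone, on 4 of 5 slides (median 0.85, camera adjusted p = 3.17e-05; adjusted p = 0.265 with an estimated correlation), among them Fkbp5, a co-chaperone of the glucocorticoid receptor (1.26 ± 0.25, adjusted p = 0.00056, other probes 0.26 to 0.96). Alternatively activated macrophage genes had 4 of 15 higher, also 4 when adjusted over the list alone (median 0.31, camera adjusted p = 0.0144; adjusted p = 0.431 with an estimated correlation), with the urea cycle enzyme Arg1 up by 1.00 ± 0.26 (adjusted p = 0.0078). Of 25 NRF2 and oxidative stress genes 6 rose and 1 fell, 10 when adjusted over the list alone (median 0.09, camera adjusted p = 0.0457; adjusted p = 0.433 with an estimated correlation), with the aldo-keto reductase Akr1b8 up by 1.24 ± 0.14 (adjusted p = 2.1e-07).

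Lymphocyte lists moved the other way at 486 µg on day 1. Of 16 B cell and plasma cell markers 6 fell and none rose, 7 when adjusted over the list alone (median -0.52, lower on all 5 slides; camera adjusted p = 1.36e-06; adjusted p = 0.219 with an estimated correlation), with the transcriptional coactivator Pou2af1 at -1.05 ± 0.18 (adjusted p = 0.00016). Of 19 T cell markers 4 fell, 6 when adjusted over the list alone (median -0.33, lower on all 5 slides; camera adjusted p = 0.000113; adjusted p = 0.347 with an estimated correlation), with the transcription factor Lef1 at -0.62 ± 0.14 (adjusted p = 0.0027). Of 22 interferon-stimulated genes 5 fell, 7 when adjusted over the list alone (median -0.47, camera adjusted p = 9.02e-06; adjusted p = 0.431 with an estimated correlation). Their median was lower on 4 of 5 slides, with replicate 1 higher, as for the interferon-induced GTPases Igtp (-1.12 ± 0.28, adjusted p = 0.0051) and Gbp2 (-0.90 ± 0.19, adjusted p = 0.0012). NK cell markers had none of 14 called, also none when adjusted over the list alone (median -0.49, camera adjusted p = 0.00244; adjusted p = 0.505 with an estimated correlation). MHC class II genes had 1 of 9 lower, 5 when adjusted over the list alone (median -0.49, camera adjusted p = 0.00127; adjusted p = 0.347 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, was at -0.61 ± 0.13 (adjusted p = 0.0013, lower on 4 of 5 slides) and Cav1, the caveolin of alveolar type 1 and endothelial cells, at -0.56 ± 0.13 (adjusted p = 0.0023).

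Several preset genes did not pass at 486 µg on day 1. Il6, above background on 4 of 5 treated arrays and on 0 of 5 controls, differed by 0.45 ± 0.17 (adjusted p = 0.082), and Il1b by 0.99 ± 0.35 (adjusted p = 0.056). Cxcl5, which was above background on 0 of 5 control arrays, differed by 0.65 ± 0.49 (adjusted p = 0.46). In the Cy5 channel after loess and quantile scaling, without a dye swap, the means of Il6 and Cxcl5 stood at least 1.4-fold and 1.66-fold above those of the controls. These figures allow for no spread and exceed the ratio folds of 1.36 and 1.57, so they are no lower limits of the change. Gpnmb, a glycoprotein of lipid-laden macrophages, differed by 0.59 ± 0.22 (adjusted p = 0.071), the collagen gene Col1a1 by 0.34 ± 0.16 (adjusted p = 0.18), fibronectin Fn1 by 0.07 ± 0.20 (adjusted p = 0.88), and the surfactant gene Sftpc by -0.56 ± 0.35 (adjusted p = 0.36). In all, 2402 genes were called, 1471 higher and 931 lower, of which 367 higher and 212 lower genes changed at least 1.5-fold. With slide as a block 3644 were called, 2081 higher and 1563 lower, and without 486 µg replicate 5 the count was 1505. By the Cy5 channel alone 1281 were higher and 1372 lower, and median centring called 230.

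**Figure D2:**
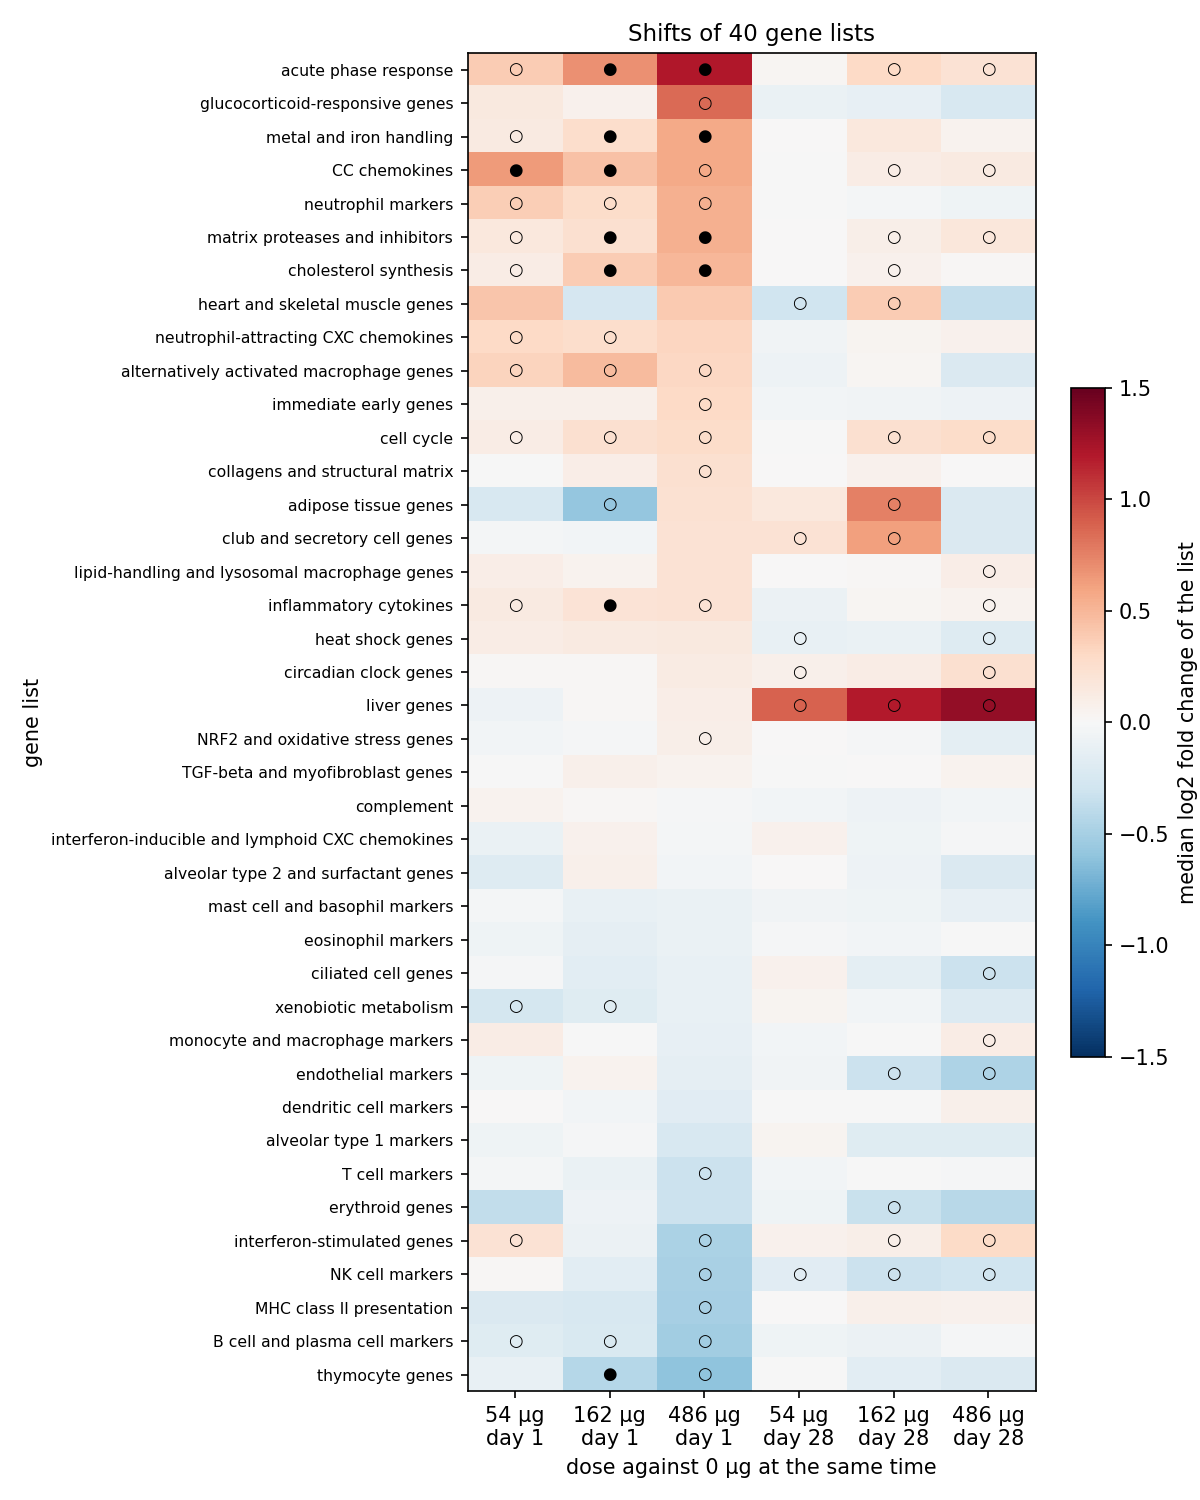
Colour gives the median log2 fold change of each of the 40 gene lists (y axis) for each dose against 0 µg on day 1 and day 28 (x axis), red for higher and blue for lower. Open circles mark lists called by camera with the preset correlation alone and filled circles those called with an estimated correlation too; 1, 7 and 4 circles are filled on day 1 and 0 on day 28.

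The doses on day 1 share their 5 controls, so overlaps between them were set against values under no effect and under split controls. At 162 and 486 µg, 206 of the 210 genes called at the lower dose were shared, 165 higher and 41 lower. Independent calls would share 12.2 and 2.05, simulated null data shared a median of 0, and controls split between the doses left a median of 44.5 (range 12 to 110). Data simulated without changed genes were bound to share almost none, so that 0 tests nothing. Split controls leave each dose with fewer controls, which lowers the number of calls as well. Across genes, which are not independent replicates, the responses to 162 and 486 µg correlated at 0.770, against 0.5 in simulated null data (covariance 0.0395 against 0.0116). At 54 and 162 µg 27 genes were shared (22 higher, 5 lower), against 0.24 and 0.011 for independent calls and a median of 1 with split controls (range 0 to 11), and the responses correlated at 0.675 against 0.498 (covariance 0.0228 against 0.0116). At 54 and 486 µg 28 were shared (23 higher, 5 lower), against 2.13 and 0.232 and a median of 1.5 (range 0 to 35). For this pair the correlation, 0.417, was below the simulated 0.496, and the covariance was 0.0208 against 0.0116. With split controls the correlation at 162 and 486 µg had a median of 0.524 (range 0.229 to 0.645). At 54 and 162 µg that median was 0.275 (range 0.101 to 0.589), and at 54 and 486 µg 0.204 (range -0.059 to 0.482). The simulated data lack any structure among the arrays, so a correlation above theirs does not by itself show a common response.

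Direct steps between doses on day 1 picked out a few genes. From 54 to 162 µg 3 genes rose: Pbp2 (1.55 ± 0.24, adjusted p = 0.0036), the prostaglandin synthase Ptgs1 (0.58 ± 0.10, adjusted p = 0.032) and Phgr1 (0.44 ± 0.08, adjusted p = 0.049). From 162 to 486 µg the metallothioneins Mt2 and Mt1 rose by 1.96 ± 0.36 (adjusted p = 0.013) and 1.22 ± 0.20 (adjusted p = 0.005), Sprr1a by 1.57 ± 0.31 (adjusted p = 0.017) and Cck, the peptide cholecystokinin, by 1.12 ± 0.18 (adjusted p = 0.005). Gata3, a transcription factor of T cells and innate lymphoid cells, fell by 0.79 on the log2 scale (SE 0.17, adjusted p = 0.036). These genes went the same way on all 5 slides. With 1 array left out, Ptgs1 and Phgr1 lost their call in 7 of 10 fits each, and Mt2, Sprr1a and Gata3 in 4, 5 and 7. The step to 162 µg had 1 gene without 54 µg replicates 1, 2 or 4 or 162 µg replicates 2 or 3, and 6 without 162 µg replicate 1, and 7 with slide as a block. The step to 486 µg had 36 genes, 33 higher and 3 lower, against 45 and 14 by the deposited value table and 454 in all with slide as a block. It had 2, 19, 61, 9 and 65 genes without 162 µg replicates 1 to 5, and 296, 10, 7, 125 and 2 without 486 µg replicates 1 to 5.

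On day 28 at 486 µg, clock genes and 2 genes of lipid-handling macrophages differed from vehicle. Dbp, a clock-controlled transcription factor, was 4.48-fold higher (2.16 ± 0.32, n = 5 per group, adjusted p = 0.00069), while Arntl, the clock activator BMAL1, was lower (-1.06 ± 0.17, adjusted p = 0.0014). Gpnmb was 2.71-fold higher (1.44 ± 0.22, adjusted p = 0.00074) and Trem2, a lipid-sensing receptor of macrophages, 2.28-fold higher (1.19 ± 0.22, adjusted p = 0.015). The clock repressor Nr1d2 was higher by 0.84 ± 0.16 (adjusted p = 0.017), and Nr1d1 by 0.98 ± 0.18 (adjusted p = 0.013) by one probe, with others at -0.03 and 0.06. Spon2, a secreted matrix protein, was lower (-1.22 ± 0.22, adjusted p = 0.012), as was Npr3, the clearance receptor of natriuretic peptides (-0.92 ± 0.18, adjusted p = 0.017). The rest of the 15 called genes were Myo5a, Stra6l, Efnb1, Lnx2, Trim8 and 2 transcripts known by accession alone, AK088332 and AK038006, named after their values were seen. All 15 went the same way on all 5 slides.

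Of the 15 genes at 486 µg on day 28, 7 were higher and 8 lower, and slide as a block gave 21. By the deposited ratio column 7 were higher and 3 lower, and with median centring 6 and 1. Calls of Dbp, Gpnmb and Arntl held with any 1 array left out, Spon2 was lost without 486 µg replicate 1, and the other named genes were lost in 4 to 9 of 10 fits. The count was 8, 7, 6 and 7 without 0 µg replicates 1 to 4, and 5, 7, 6 and 30 without 486 µg replicates 1, 2, 3 and 5. At 54 and 162 µg limma called 0 genes, with 110 and 1327 at an unadjusted p under 0.05 and 1 each with slide as a block. None of the acute phase and matrix transcripts named above for day 1 passed at 486 µg on day 28. Saa3 differed by 1.72 ± 0.74 (adjusted p = 0.5), Lcn2 by 1.33 ± 0.46 (adjusted p = 0.47), Cxcl1 by 1.06 ± 0.30 (adjusted p = 0.36), Timp1 by 0.39 ± 0.44 (adjusted p = 0.78), Spp1 by 0.24 and Col1a1 by 0.04. Steps between adjacent doses on day 28 called 0 genes by limma, with 801 and 180 at an unadjusted p under 0.05 and 0 with slide as a block.

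Liver transcripts were present on some treated day 28 arrays. Alb, serum albumin of liver, reached a log2 ratio of 4.31, 4.65 and 3.62 on the highest array at 54, 162 and 486 µg, against at most 0.6 in day 28 controls and 0.51 on day 1 at 486 µg. With the 7 arrays whose Alb lay more than 1 above the mean of these controls left out, a fit added after the values were seen, 3 genes were called at 486 µg, with Gpnmb at 1.74 ± 0.26 (adjusted p = 0.0018) and Dbp at 2.23 ± 0.43 (adjusted p = 0.071). Trem2 lost its call in that fit (1.12 ± 0.28, adjusted p = 0.21) and with liver genes as a covariate (1.12 ± 0.24, adjusted p = 0.068). Camera called the liver list at all 3 doses, with medians of 0.88, 1.20 and 1.32 (adjusted p = 0.000123, 0.000543 and 0.0243; adjusted p = 0.949, 0.597 and 0.544 with an estimated correlation). At 162 µg camera also called heart and muscle genes (median 0.38, camera adjusted p = 0.015; adjusted p = 0.807 with an estimated correlation) and adipose genes (median 0.75, camera adjusted p = 0.00322; adjusted p = 0.597 with an estimated correlation), higher on 3 and 4 of 5 slides. Controls varied as widely. The heart and muscle median of an array reached 3.52 in day 28 controls and 2.38 at 162 µg. For adipose genes the highest was 2.26 in day 28 controls, 4.23 in day 1 controls and 2.9 at 162 µg.

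With the liver, muscle and adipose lists counted in, camera called 6, 13 and 14 lists on day 28 at 54, 162 and 486 µg, and none held with an estimated correlation. The 6 lists at 54 µg became 3 without 54 µg replicate 1 and 10 without 0 µg replicate 4. At 486 µg, of 17 clock genes 3 rose and 1 fell, 8 passing when adjusted over the list alone (median 0.24, camera adjusted p = 0.00218; adjusted p = 0.182 with an estimated correlation). Of 26 lipid-handling and lysosomal macrophage genes 2 rose, 5 when adjusted over the list alone (median 0.10, camera adjusted p = 0.000911; adjusted p = 0.428 with an estimated correlation). Endothelial markers had none of 20 called, also none when adjusted over the list alone, and a median of -0.46 that was lower on all 5 slides (camera adjusted p = 1.31e-07; adjusted p = 0.428 with an estimated correlation). Replicates 2 and 4 stood lowest, with endothelial medians of 4.15 and 3.8 per array against 4.7 to 5.04 on the other 3 arrays and 4.87 to 5.31 in controls. Interferon-stimulated genes had none of 22 called, 1 when adjusted over the list alone, and a median of 0.29 that was higher on all 5 slides (camera adjusted p = 1.31e-07; adjusted p = 0.428 with an estimated correlation). Cell cycle genes had none of 31 called, also none when adjusted over the list alone (median 0.28, camera adjusted p = 1.52e-06; adjusted p = 0.475 with an estimated correlation). Under other scalings the medians of NK cell and ciliated cell genes changed sign at this dose, NK cell markers from -0.30 to as much as 0.08 and ciliated cell genes from -0.33 to 0.02. That of heat shock genes went from -0.19 to 0.18 only under median centring, where the median of all genes was 0.17.

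**Figure D3:**
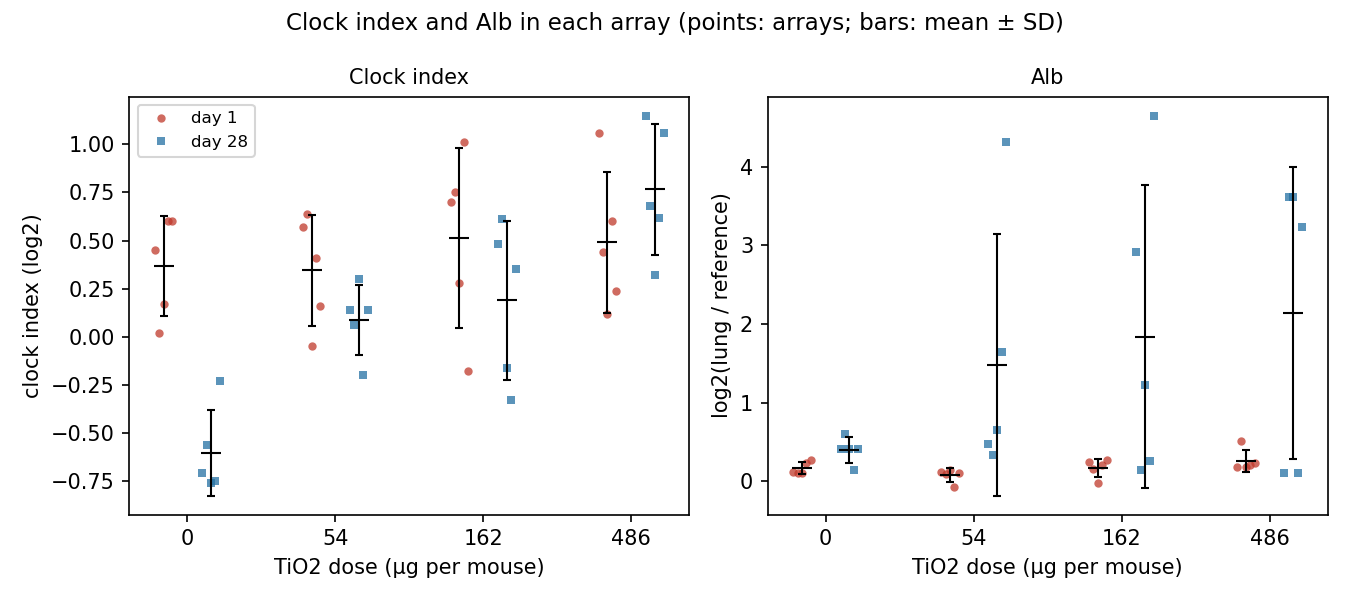
Per array, a clock index (mean log2 ratio of Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Per3 minus that of Arntl, Npas2 and Clock) on the left and the log2 ratio of Alb on the right, against dose in µg per mouse (x axes, evenly spaced, not to scale), with circles for day 1, squares for day 28 and bars for the mean and standard deviation of 5 arrays. On day 28 the mean index was -0.60 at 0 µg and 0.76 at 486 µg, and the highest Alb value was 0.6 at 0 µg and 4.65 at 162 µg.

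The response to 486 µg differed between the days for 544 genes by the test of the difference itself, 147 higher and 397 lower on day 28, and slide as a block gave 1071. By the Cy5 channel alone 335 were higher and 368 lower, and with median centring 8 and 12. Saa3 (-4.37 ± 1.05, adjusted p = 0.015), Timp1 (-4.04 ± 0.62, adjusted p = 0.00018), Mt2 (-3.71 ± 0.51, adjusted p = 6.3e-05) and Pbp2 (-3.28 ± 0.34, adjusted p = 3.5e-07) had smaller responses on day 28, and Dbp a higher one (2.44 ± 0.45, adjusted p = 0.0015). Most of the Dbp difference lay in the vehicle mice, with means of 0.77 on day 1 and -1.04 on day 28, against 0.49 and 1.12 at 486 µg. Of 21 cholesterol synthesis genes 10 were called lower in this difference, 14 when adjusted over the list alone (median -0.56, camera adjusted p = 1.46e-12), the one list whose call held with an estimated correlation (adjusted p = 0.00165). At 162 µg the difference was called for 11 genes, all lower on day 28, and for 33 with slide as a block. Pbp2 (-1.98 ± 0.34, adjusted p = 0.012) was called in every fit with 1 array left out. The count at 162 µg was 3 and 4 without day 1 0 µg replicates 2 and 5, and 5, 4, 4 and 6 without day 1 162 µg replicates 2 to 5. It was 6, 7 and 5 without day 28 0 µg replicates 1, 4 and 5, and 2, 7 and 5 without day 28 162 µg replicates 2, 3 and 5. At 54 µg limma called 0 genes, 780 at an unadjusted p under 0.05 and 0 with slide as a block. Without day 1 486 µg replicate 5 the count at 486 µg was 302, and without day 1 54 µg replicate 1 that at 54 µg was 9.

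Of the 2402 genes called at 486 µg on day 1, 1590 (66.2%) kept their sign on day 28, and their median absolute log2 difference was 0.43 on day 1 and 0.09 on day 28. These genes were selected by their day 1 calls, which by itself favours the larger day 1 median. Neither the share nor the medians were set against those of all genes, so no conclusion about a decline is drawn from them. Calls of both days shared Npr3 (-0.56 and -0.92) and Stra6l (0.55 and 0.70), against 0.514 higher and 0.372 lower genes for independent calls. Between the days in vehicle mice, Dbp alone was called, lower on day 28 (-1.81 ± 0.29, adjusted p = 0.0081), with 498 genes at an unadjusted p under 0.05. That call ended without day 28 replicates 1 or 4 or day 1 replicate 5, and 4 genes were called without day 1 replicate 2.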

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

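The random splits of the arrays and the tests of liver RNA and liver tissue were planned before the values they measure were seen, while the tests of time of day, of dose, of dilution, of glucocorticoid response and of single arrays and the splits within slides were chosen afterwards.

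The first pattern is the shift of clock genes on day 28. The clock index (phase genes such as Dbp minus Arntl, Npas2 and Clock) was -0.60 ± 0.22, 0.09 ± 0.18, 0.19 ± 0.41 and 0.76 ± 0.34 at 0, 54, 162 and 486 µg (SD, n = 5 each). Liver RNA in the treated samples is argued against as the whole cause, since the shift at 486 µg was 1.36 ± 0.21 (SE) with 4 liver genes as a covariate and 1.37 without. Sampling of the control mice at another time of day may account for the shift, because the 54 µg group, with no called gene, shows 0.506 of the shift at 486 µg, and because the index of day 28 controls minus that of day 1 controls was -0.97 (exact two-sided permutation p = 0.00794). Both dose shifts are taken against the same 5 day 28 controls, so low values of these controls for any reason would raise that share. A dose-dependent effect on clock genes stays open too, with the index 0.68 higher at 486 than at 54 µg (exact two-sided permutation p = 0.00794). That p is the lowest that 5 against 5 arrays can give. The index holds Dbp, Nr1d1, Nr1d2 and Arntl, which were called at 486 µg on day 28, so selection by itself favours a large shift at that dose. Neither the share of 0.506 nor the 0.68 is therefore independent evidence for a cause.

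The second pattern is the fall of lymphocyte and interferon-stimulated genes at 486 µg on day 1. A minority of the genes of these lists was called, and the lists lost their camera calls with an estimated correlation. Dilution of resident cells by incoming cells was not settled as a cause. The T cell, B cell and interferon lists shifted by -0.40 relative to the endothelial and alveolar lists (exact two-sided permutation p = 0.0397), at -0.48 and -0.09 on their own. With slide as a block over the 20 day 1 arrays the difference was -0.40 ± 0.16 (SE, 95% interval -0.74 to -0.05). It was lower on 4 of 5 slides and 0.11 higher on the slide of replicate 1, with a sign-flip p over slides of 0.125, where 5 slides can give 0.0625 at the lowest. The 3 immune lists were chosen after they were seen to fall, which by itself favours such a difference, so it cannot decide about dilution. A single array does not carry the fall, which stayed between -0.60 and -0.43 without any 1 array of the group, although replicate 1 of the group lies the other way for interferon genes. A glucocorticoid response of the dosed mice is a candidate explanation that stays open: over the 20 day 1 arrays, deviations from group means of glucocorticoid-responsive genes and of the immune lists correlated at r = -0.80 (permutation p = 0.00083; rho -0.79, permutation p = 0.00096; adjusted p = 0.0027 over 4 relations). That r was -0.78 without the 2 farthest arrays, -0.68 without 486 µg replicate 1, -0.87 with scan day and -0.85 with slide removed, and -0.31 on day 28 (permutation p = 0.174).

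The third pattern is liver transcripts on 7 treated day 28 arrays, 2, 2 and 3 at 54, 162 and 486 µg, counted where Alb lay more than 1 above the mean of the day 28 controls. The number depends on that limit: 54 µg replicate 4, at 1.64, is counted and 162 µg replicate 3, at 1.22, is not, though the mean of 4 liver genes was 1.13 and 1.1 on them. Replicate 5 of the day 1 controls had a mean of 1.11 with Alb at only 0.27, so that mean alone does not mark liver RNA. Of a second list of 36 liver genes, 22 were measured and 14 (63.6%) correlated over 0.5 with Alb across the day 28 arrays, against 1.96% of all genes, which lies between the bounds set in advance for and against liver tissue carried into the lung sample. Lung, liver and heart were taken from the same mice, and carry-over may explain the pattern but was not settled by that value. A dose effect was not settled either, with the 4 liver genes 0.49 higher at 486 than at 54 µg (exact two-sided permutation p = 0.635). Against 0 µg these genes differed by 1.07, 1.51 and 1.56 at the 3 doses (exact two-sided permutation p = 0.0317, 0.135 and 0.159).

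Among random splits of the same arrays, the real one included, chance can be excluded at 162 µg on day 1 (210 genes, 1 of 100 splits as large, highest other 132) and at 486 µg on day 1 (2402, 1 of 100, highest other 704). At 486 µg on day 28 it can be excluded only for the fit without slides (15, 1 of 100, highest other 4), as within slides 2 of 16 splits called as many as the real 21. For the difference between days at 162 µg (11, 1 of 100, highest other 1) and 486 µg (544, 2 of 100, highest other 716) it can likewise be excluded only for the fit without slides, as no splits within slides were run there. At 486 µg that highest other is larger than the real count, so the exclusion there rests on the share of splits alone. For day 28 against day 1 in vehicle mice 1 of 100 splits was as large (1 gene, highest other 0), but this rests on Dbp alone. The count ran from 0 to 4 with 1 array left out. Each slide held a single day, so day cannot be told apart from slide in this comparison, and no conclusion is drawn from its splits. Chance cannot be excluded for the 34 genes at 54 µg on day 1, as 7 of 100 splits called as many. Their highest other, 1928, is many times the real count and points to a structure among the arrays. The same holds for the day 1 steps to 162 µg (3 genes, 9 of 100, highest other 647) and to 486 µg (36, 9 of 100, highest other 1333). For the day 28 step to 486 µg the real count is 0, which all 100 splits reach, so the splits test nothing there, but the highest other, 4940, points to a structure too. The random splits take no account of slides. The one with 1928 genes set slides 1 and 5 against 7 and 9, and that with 1333 slides 5 and 9 against 1 and 7. The split with 1333 genes also kept on one side the arrays with the highest means of glucocorticoid-responsive genes. These were 0.68 and 0.7 for 162 µg replicates 3 and 5 and 0.99, 1.06 and 1.37 for 486 µg replicates 2, 3 and 5, against -0.5 to 0.61 for the rest. That with 4940 set slides 4 and 6 against 2 and 10, but slide is not all that it follows: it and the next largest, with 4513 and 3837, each keep on one side the 4 arrays with the lowest endothelial and alveolar lists (3.86 and 3.35 for 162 µg replicates 2 and 3, 3.62 and 3.38 for 486 µg replicates 2 and 4, against 4.15 to 4.43 for the other 6). For the remaining counts of 0, all 100 splits reach them and test nothing, with highest others of 1 at 54 and 162 µg on day 28, 6 for the difference between days at 54 µg and 2 for the day 28 step to 162 µg.

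With arrays swapped only within slides and slide as a block there are 16 splits per comparison, too few for a share under 0.05. The real counts on day 1 at 54, 162 and 486 µg were 163, 492 and 3644, with highest others of 10, 19 and 1048. On day 28 they were 1, 1 and 21, with highest others of 3, 0 and 56. For the day 1 steps to 162 and 486 µg they were 7 and 454, with highest others of 119 and 0, and for those of day 28 they were 0 and 0, with highest others of 0 and 1302.

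For the numbers of shifted lists, the random splits do not exclude chance at any dose or day. These splits take no account of slides, and splits within slides were not run for lists. On day 1, 11, 22 and 9 of 100 splits called as many lists as the real 13, 14 and 19, with highest others of 19, 19 and 24. On day 28, 39, 19 and 17 of 100 splits did so for the real 6, 13 and 14, with highest others of 15, 17 and 20. The other splits called medians of 5, 10 and 11 lists on day 1 and 5, 7 and 8 on day 28. Camera at the preset correlation thus commonly called several lists in random splits, so its adjusted p-values are likely too small for these arrays.

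Of 367 sets of 5 arrays, 31 held an array far from the other 4 by Dixon's criterion (ratio above 0.71), where chance gives about 1 in 20. Replicate 1 of the 486 µg group on day 1 was such an array for Gbp3 (log2 ratio 2.01, others 0.04 to 0.58), Ltb (-0.07, others -1.24 to -0.92), Ccl8 (2.58, others 1.16 to 1.44), Col4a2 (1.27, others 2.11 to 2.38), Osgin1 (0.45, others 0.68 to 0.77), Cfp (1.43, others 0.12 to 0.43), Ifi44 (-0.33, others -1.84 to -1.53), Rtp4 (1.19, others -0.30 to -0.15) and Per1 (-0.53, others 0.73 to 1.11). In the same group, replicate 2 stood apart for Hamp (0.32, others 1.42 to 1.80) and replicate 4 for Gstm1 (2.68, others 1.81 to 2.04). At 54 µg on day 1, replicate 1 stood apart for Saa3 (-3.20, others 2.02 to 3.41) and Lcn2 (0.88, others 3.75 to 4.16), and replicate 3 for Phgr1 (0.54, others 0.11 to 0.22). At 162 µg on day 1, replicate 4 stood apart for Gata3 (-1.22, others -0.67 to -0.49).

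Among day 1 controls, replicate 1 stood apart for Il33 (2.03, others 1.55 to 1.66), Osgin1 (0.72, others -0.06 to 0.09), C1s1 (-0.29, others 0.47 to 0.77) and Cd74 (2.60, others 3.18 to 3.37). Replicate 2 did so for Neat1 (2.76, others 2.30 to 2.40), Per1 (-1.14, others -0.38 to -0.15), Hspb1 (1.69, others 1.18 to 1.31) and Myc (-3.36, others -2.96 to -2.84). Replicate 3 did so for Igtp (3.62, others 1.49 to 1.75), Gbp2 (3.17, others 2.29 to 2.46) and Cyp1a1 (0.33, others 0.12 to 0.18), and replicate 5 for Ms4a1 (1.44, others 0.57 to 0.78) and Sftpc (6.67, others 7.39 to 7.54). Among day 28 controls, replicate 3 stood apart for Il6 (-0.75, others -1.20 to -1.10), replicate 4 for Sftpc (8.02, others 6.73 to 7.08) and replicate 5 for Timp1 (-2.66, others -3.18 to -3.05).

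Responses differed between the days for 11 genes at 162 µg and 544 at 486 µg by the test of the difference. At 162 µg the day 28 minus day 1 difference was -3.12 for Timp1 (adjusted p = 0.034), -2.68 for Saa1 (adjusted p = 0.02), -1.98 for Pbp2 (adjusted p = 0.012), -1.23 for Ctps (adjusted p = 0.02) and -1.03 for 2200002D01Rik (adjusted p = 0.012). With 1 array left out, the calls of Timp1, Saa1 and Ctps at 162 µg ended in 15, 6 and 3 of 20 fits. At 486 µg it was -4.37 for Saa3 (adjusted p = 0.015), -4.04 for Timp1 (adjusted p = 0.00018), -3.71 for Mt2 (adjusted p = 6.3e-05), -3.28 for Pbp2 (adjusted p = 3.5e-07), -3.16 for Saa1 (adjusted p = 3e-04) and -1.91 for Ccl2 (adjusted p = 0.017). It was -1.51 for Tnc (adjusted p = 0.011), -1.46 for 2200002D01Rik (adjusted p = 5.3e-06) and -1.40 for Ctps (adjusted p = 0.00036). It was 2.44 for Dbp (adjusted p = 0.0015), 1.77 for Ifi27l2a (adjusted p = 0.035), 1.49 for Gbp3 (adjusted p = 0.035), 1.38 for Ms4a1 (adjusted p = 0.015) and 1.36 for Gbp8 (adjusted p = 0.0017). The calls of Ifi27l2a and Gbp3 ended in 10 of 20 fits each. The median of the cholesterol synthesis genes differed by -0.557 (camera adjusted p = 1.5e-12).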

How the results depend on the processing

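Fits with liver or clock genes as a covariate, and without the arrays holding liver transcripts, were chosen after the data were seen; the other settings were planned. No named gene that was called changed sign under any planned setting: of 4645 values, 3925 kept sign and call, 662 lost and 21 gained a call, and 37 uncalled values changed sign. Of 138 values under the added settings, 83 kept sign and call, 47 lost a call and 8 uncalled values changed sign. Under other scalings, medians of lists called on day 1 kept their sign, while on day 28 those of 3 of 13 lists at 162 µg (endothelial, cholesterol synthesis and matrix protease genes) and 3 of 14 at 486 µg changed sign, heat shock genes only under median centring. Of the values kept, 205 come from loess with quantile scaling, which leaves the ratios as they were and so tests nothing. Among 205 values per setting, median centring lost 118 calls and a fit of only the groups compared 59. Counts that moved by more than 1.5 times follow, with the reported counts in parentheses, and the cause was not tested unless fewer arrays or a stricter threshold are part of the setting.

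With slide as a block, genes called were 163 (34), 492 (210) and 3644 (2402) on day 1 at 54, 162 and 486 µg, 1 (0) and 1 (0) on day 28 at 54 and 162 µg, 33 (11) and 1071 (544) for the difference between days at 162 and 486 µg, and 7 (3) and 454 (36) for the day 1 steps to 162 and 486 µg. With scan day as a block they were 53 (34) at 54 µg on day 1, 26 (11) for the difference at 162 µg and 83 (36) for the step to 486 µg. Median centring, which moved the median of all genes to 0.11 and 0.17 at 162 and 486 µg on day 28, gave 2, 11 and 230 on day 1, 7 (15) at 486 µg on day 28, 0 and 20 for the differences, and 1 and 2 for the day 1 steps. Without background subtraction there were 52 and 332 at 54 and 162 µg on day 1, 17 and 858 for the differences, 87 for the step to 486 µg and 4 (1) between days in vehicle mice. The ratio column gave 56 at 54 µg on day 1, 33 and 861 for the differences and 1 (0) for the day 28 step to 162 µg. The value table gave 327 at 162 µg on day 1, 35 and 848 for the differences, 59 for the step to 486 µg and 4 between days. The Cy5 channel alone gave 87 at 54 µg on day 1, 8 at 486 µg on day 28, 5 for the step to 162 µg and 3 between days, and the mean of a gene's probes gave 8 at 486 µg on day 28.

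At least 1.5-fold were 16, 62 and 579 genes on day 1, 324 for the difference at 486 µg and 1 and 17 for the day 1 steps. Shared genes at that size were 11 (27) for 54 and 162 µg, 11 (28) for 54 and 486 µg, 58 (206) for 162 and 486 µg and 0 (2) for 486 µg on both days. Over all called genes, whatever their fold, controls split between the doses gave medians of 1 (27), 1.5 (28) and 44.5 (206) for the first 3 pairs. A fit of only the groups compared, with fewer arrays, gave 7 and 100 at 54 and 162 µg on day 1, 3 at 486 µg on day 28, 2 (0) for the difference at 54 µg, 0 and 0 for the day 1 steps and 5 between days. Without the arrays holding liver transcripts there were 3 genes at 486 µg on day 28, 7 and 261 for the differences, and 3, 8 and 8 lists on day 28. The liver covariate gave 8 genes at 486 µg on day 28, 38 for the difference at 162 µg and 4 lists at 162 µg. The clock covariate gave 55 genes at 486 µg on day 28 and 1 and 4 lists at 54 and 486 µg; of the 15 genes it kept Npr3 (-1.34). Dbp went from 2.16 to 0.17 ± 0.21, Arntl from -1.06 to -0.05, Nr1d1 from 0.98 to 0.02 and Nr1d2 from 0.84 to 0.17, as they are part of the index. Other calls ended with the fold little changed, Gpnmb at 1.35 ± 0.34 (1.44 before, adjusted p = 0.058), Efnb1 at -0.72 (-0.63), Lnx2 at -0.48 (-0.54), Myo5a at 0.69 (0.73), Stra6l at 0.64 (0.70) and Trim8 at -0.41 (-0.39), or with a smaller one, Trem2 at 0.72 (1.19), Spon2 at -0.86 (-1.22), AK088332 at -0.64 (-1.06) and AK038006 at -0.24 (-0.4).

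With an estimated correlation, lists called were 1 (13), 7 (14) and 4 (19) on day 1 and 0 (6), 0 (13) and 0 (14) on day 28. The fry test called 3 at 54 µg on day 1 and 0, 0 and 0 on day 28, and no filter on dim probes gave 2 at 54 µg on day 28. At 162 and 486 µg on day 1 the fry counts moved less, to 10 (14) and 18 (19). With 1 array left out, genes ranged over 10 to 81, 94 to 218 and 1505 to 2715 on day 1, 0 to 0, 0 to 1 and 5 to 30 on day 28, 0 to 9, 2 to 15 and 302 to 810 for the differences, 1 to 6 and 2 to 296 for the day 1 steps, 0 to 0 for those of day 28 and 0 to 4 between days. Lists ranged over 7 to 15, 12 to 20 and 16 to 23 on day 1 and 3 to 10, 9 to 15 and 11 to 18 on day 28. No paired analysis was possible because the labels give no replicate numbers that pair mice; arrays of different doses on 1 slide were compared within it by the slide block, whose counts are given above. Signal over background limits what can be compared: 26567 of 41174 probes passed. The changes of Il6 and Cxcl5 at 486 µg on day 1 are uncertain in size, as their control signals were not above background.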

Other observations

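Other groups of the day 1 response at 486 µg round off the picture of the tissue. Of 17 immediate early genes 5 rose, also 5 when adjusted over the list alone (median 0.30, camera adjusted p = 0.00734; adjusted p = 0.431 with an estimated correlation), among them the growth regulator Myc at 0.81 ± 0.18 (adjusted p = 0.0023), higher on all 5 slides. Of 12 inflammatory cytokines 2 rose, 6 when adjusted over the list alone (median 0.22, camera adjusted p = 0.0457; adjusted p = 0.308 with an estimated correlation), with Il33 at 1.28 ± 0.20 (adjusted p = 3e-05). Of 26 lipid-handling and lysosomal macrophage genes 6 rose and 3 fell, 14 when adjusted over the list alone (median 0.22, camera adjusted p = 0.0602), with osteopontin Spp1 up by 1.54 ± 0.34 (adjusted p = 0.002) and galectin 3, Lgals3, by 1.24 ± 0.20 (adjusted p = 6.8e-05). Of 21 TGF-beta and myofibroblast genes 4 rose and 2 fell (median 0.06, camera adjusted p = 0.278), with the pericyte receptor Pdgfrb at -0.50 ± 0.12 (adjusted p = 0.0051). Of 4 thymocyte genes 2 fell, 3 when adjusted over the list alone (median -0.61, camera adjusted p = 0.0211; adjusted p = 0.151 with an estimated correlation).

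Epithelial and endothelial lists were not called on day 1 at 486 µg. Alveolar type 1 markers had 1 of 11 higher and 1 lower (median -0.24, camera adjusted p = 0.322), with the type 1 cell glycoprotein Pdpn higher by 0.68 ± 0.15 (adjusted p = 0.0022). Alveolar type 2 and surfactant genes had 1 of 15 higher (median -0.04, camera adjusted p = 0.918). Ciliated cell genes had none of 20 called (median -0.11, camera adjusted p = 0.382), club and secretory cell genes none of 18 (median 0.22, camera adjusted p = 0.939) and endothelial markers none of 20 (median -0.13, camera adjusted p = 0.289). Clock genes had 3 of 17 higher (median 0.13, camera adjusted p = 0.278) and heat shock genes 2 of 14 higher (median 0.15, camera adjusted p = 0.112).

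Across genes, the responses to 162 and 486 µg on day 28 correlated at 0.751, where simulated null data with shared controls gave 0.497 and split controls a median of 0.425, though limma called 0 genes at 162 µg (1327 at an unadjusted p under 0.05, 1 with slide as a block). Both groups held arrays with low endothelial and alveolar lists and arrays with liver transcripts, a structure that the simulated data lack. The correlation therefore does not show a common response to the particles. The responses to 54 and 162 µg on day 28 correlated at 0.398 against 0.502 in the simulated data. Genes are not independent replicates in these correlations.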
